A study of Mus musculus with 4 samples.

How the data were processed

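AGO2 HITS-CLIP was done by the submitters on mouse Th2 cells of wild-type genotype and of a genotype lacking Mirc11 and Mirc22. Per the labels' protocols, CD4 T cells from spleen and lymph nodes were polarised in culture, crosslinked with ultraviolet light and lysed, AGO2 was precipitated with an antibody, and the bound RNA was ligated to linkers, size-selected on a gel, reverse transcribed and amplified. The submitters' processing notes name cutadapt, Bowtie2 and SAMtools, without versions, and the genome build mm10. Per the labels and the series design, DeepRNA-Reg, a deep-learning method that compares a pair of CLIP experiments, produced the loci. Its version, thresholds and filters, any removal of duplicate reads and any pooling of libraries are not given in the sources used here. Each of these steps could change which loci are listed.

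The authors deposited 2 tables, 1 per direction, with position, strand, gene label, RNA sequence and a score per locus, the differential binding enrichment (DBE). Its scale and normalization are not stated in the file headers. Each deposited table also gives the percentile of that score within its own list and a quality score (QS) from 1 to 10, which bins the percentile. DBE was used only to describe, rank and filter loci within a list. Positions were read as counted from 0 with a closed end, since locus starts and stops at gene boundaries lay 1 base below the annotated ones far more often than on them (218 starts against 9 and 242 stops against 1 in the WT list). They were given 1-based, with 1 added to both ends. The gene table was of GRCm38, the assembly also called mm10, and matched 97.3% of gene labels of the WT list and 97.4% of those of the KO list. It has no exons, UTRs or sequence.

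The tables compare Th2 cells, with 1 sample per genotype, so no test across samples, no paired fit and no leaving out of replicates could be made. Fisher's exact tests (two-sided) compare the lists, and odds ratios are WT list over KO list with 95% intervals. Loci of one gene are not independent, and an interval from resampling genes 1000 times was computed beside each family's odds ratio. Shares have exact Clopper-Pearson intervals. Adjusted p values are Benjamini-Hochberg with a threshold of 0.05. Intervals cover counting error only.

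Seed sites of 20 microRNA families (3 deleted, 17 others) were searched on the RNA sequence of each locus. A 7mer-m8 site is the reverse complement of nucleotides 2 to 8 of the mature strand, a 6mer that of nucleotides 2 to 7, and 8mer and 7mer-A1 sites add an A opposite nucleotide 1. Mature sequences were taken from background knowledge. For 7-mer ranks, 0.5 was added to each count. DBE with and without a match was compared by the difference of medians with 100000 permutations. Gene lists were tested by whether members had more WT-list than KO-list loci, among genes with a locus, with equal numbers counted as no excess. Dinucleotide-preserving shuffles (100 per locus, with 10 random seeds), a gene bootstrap of 1000 draws and Mantel-Haenszel odds ratios stratified by width or gene were used for the tests of explanations.

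The main tests, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are those of the 15 loci with the highest DBE in each list, 1 per gene. To these are added the 10 highest WT-list loci with a match of each deleted family, the 5 highest KO-list loci with any such match, up to 4 genes per fixed gene list and list of loci, and the deleted microRNA genes. Any other gene is said to have been chosen after its values were seen. Some genes that this rule takes are not reported here.

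The alternatives set beforehand and run were 6mer, 8mer and 7mer-A1 sites, the opposite strand, loci from the 50th and the 90th percentile of DBE upward, 1 locus per gene, merged loci, loci free of overlap, other definitions of overlap, and mean ranks in place of medians. Annotation classes, wider or fixed search windows, restriction to 3' UTRs or exons and flanking background for site position need a genome or transcript models and were not run. The position of sites was therefore compared between the lists in place of flanks. Alternatives chosen after seeing the data were stratification by width and by gene, shuffling, leaving out the 20 genes with most matching WT-list loci, the central 20 bases, loci within 5 kb of the gene end, loci outside the reported targets, common 7-mers, width-adjusted DBE, long noncoding RNAs without Kcnq1ot1, and site position and matching loci of the reported targets from the 50th percentile of DBE upward. RNA classes, matching loci per gene list and the alternatives for miR-155 were also added after seeing the data. Ties among the 20 genes left out were taken in order of symbol, so other genes with 2 matching loci stayed in.

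The tests were also run on simulated data. With loci reassigned to the lists at random, 0 of 400 family tests passed. Single loci were reassigned, which breaks their grouping by gene, so this did not check the effect of that grouping. After random reassignment of the 85339 loci, a miR-27 site was implanted in 200 loci, all in the simulated WT list. The miR-27 family was then called in 20 of 20 simulated lists, and the implanted 7-mer ranked 3 or better in each of 5 lists. Of tests of other families, 0 of 360 passed. This count leaves out miR-128, whose site overlaps that of miR-27, so false calls of miR-128 were not checked. Among 7462 genes, 6 of 200 random gene lists and 200 of 200 lists made to differ had p under 0.05. Random gene lists were not matched to the fixed lists in loci per gene. The permutation test passed in 2 of 20 unchanged sets and in 20 of 20 sets raised by 5 on the DBE scale. Stratified intervals included 1 in 19 of 20 simulations for width and 19 of 20 for gene. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1.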

Results

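AGO2 HITS-CLIP recovers short RNA fragments that ultraviolet light has crosslinked to AGO2, the Argonaute protein that carries microRNAs to their target RNAs. The series holds 4 mouse samples, 1 per group: Th2 cells of wild-type genotype (WT), Th2 cells that lack the microRNA clusters Mirc11 and Mirc22 (KO), and freshly isolated CD4 T cells of each genotype. Both clusters encode members of the miR-23, miR-24 and miR-27 families. The Th2 cells were CD4 T cells activated for 3 days with 500 U/mL of IL-4 and then grown for 2 days with 20 U/mL of IL-2. The 2 fresh CD4 samples were not analysed here. The measurements are 2 tables of loci with gene labels, RNA sequences and the authors' differential binding enrichment (DBE): loci with more AGO2 binding in WT than in KO Th2 cells (the WT list), and loci with more in KO (the KO list). The WT list held 44518 loci covering 1427144 bases, with a median width of 29 bases (interquartile range 20 to 40). The KO list held 40821 loci covering 1238256 bases, with a median width of 28 bases (19 to 38). Read depth is unknown, since the tables give no read counts, and there are no replicates. Every test below therefore compares the 2 lists of loci, not the genotypes, and its interval covers counting error only.

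The first question was whether the deleted microRNA genes themselves carried AGO2 binding, as a check of the genotype labels. None of the 6 deleted hairpins (Mir23a, Mir27a and Mir24-2 of Mirc11 on chromosome 8; Mir23b, Mir27b and Mir24-1 of Mirc22 on chromosome 13) overlapped a locus of either list, so the tables did not check the labels in this way. Around Mirc22, all loci carried the gene label 2010111I01Rik, the gene also called Aopep. Between the outermost Mirc22 hairpins (chromosome 13, 63300484 to 63301275, mm10) lay 1 WT-list locus, at 63300948 to 63300989, and 0 KO-list loci. Within 5 kb below the cluster lay 6 WT-list loci and 1 KO-list locus, and within 5 kb above it lay 2 WT-list loci and 7 KO-list loci. Within 5 kb of Mirc11 (chromosome 8, 84208518 to 84208921) the 3 WT-list and 4 KO-list loci all carried the label of the neighbouring gene Zswim4. These counts were not tested, and Zswim4 was chosen after its values were seen.

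**Figure D1:**
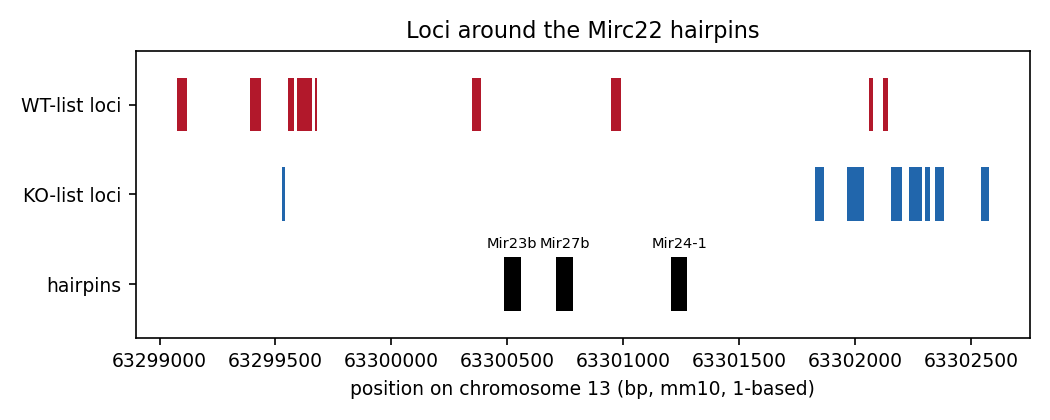
Loci of the WT list and of the KO list on chromosome 13 (position in bp, mm10) around the 3 hairpins of Mirc22; each bar is 1 locus or hairpin. The WT list has 6 loci below the cluster, 1 inside it and 2 above it, the KO list has 1 below and 7 above it, and 0 loci overlap a hairpin.

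The next question was whether the 2 directions of the comparison fell on different genes. They fell almost entirely on the same genes: of 7462 genes with a locus, 7289 (97.7%) had loci in both lists, 98 in the WT list only and 75 in the KO list only. Listed DBE went down to 0.0305 in the WT list and 0.00269 in the KO list, so presence in both lists may say little about a gene. More WT-list than KO-list loci were found in 3286 genes, more KO-list loci in 2153, and equal numbers in 2023. The long noncoding RNAs Kcnq1ot1 and Neat1 and the mRNA of Tnrc6b, an Argonaute partner in silencing, held the most WT-list loci. Kcnq1ot1, an antisense RNA of an imprinted domain, had 121 WT-list and 65 KO-list loci, Neat1, which builds nuclear paraspeckles, had 71 and 66, and Tnrc6b had 62 and 60. These 3 genes were chosen after their values were seen. No locus of the WT list shared a base with a locus of the KO list, but 68.8% of WT-list loci (95% Clopper-Pearson interval 68.4 to 69.3%) lay within 100 bases of a KO-list locus on the same strand. Of the loci whose gene label matched the gene table, 91.2% in the WT list and 90.9% in the KO list lay within 5 kb of the annotated 3' end of the gene, at median distances of 1166 and 1191 bases. Exon, intron and UTR classes were not analysed here.

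Among RNA classes, protein-coding genes took 98.1% of WT-list and 98.2% of KO-list loci with a matched label. Long noncoding RNAs took 483 loci (1.11%) of the WT list and 362 (0.907%) of the KO list, an odds ratio of 1.23 (1.07 to 1.41; two-sided Fisher's exact test, Benjamini-Hochberg adjusted exact p = 0.0181 over 5 classes). This direction turned among loci from the 50th percentile of DBE upward, with an odds ratio of 0.774 (adjusted exact p = 0.0444). The call rested on 1 gene: without Kcnq1ot1, a test added after the data were seen, the counts were 362 and 297, an odds ratio of 1.12 (0.960 to 1.31; adjusted exact p = 0.397). Transcribed pseudogenes, rRNA and snoRNA genes did not pass the same test (adjusted exact p = 0.258, 0.507 and 0.507).

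The central question of the design was whether sites of the deleted microRNAs lay where AGO2 binding was higher in WT cells. All 3 deleted families had seed matches in a larger share of WT-list than of KO-list loci. A match to nucleotides 2 to 8 (7mer-m8) of any deleted family stood in 875 WT-list loci (1.97%, 1.84 to 2.10%) in 790 genes, against 328 KO-list loci (0.804%, 0.719 to 0.895%) in 317 genes, an odds ratio of 2.48 (2.18 to 2.81; two-sided Fisher's exact test, exact p = 1.15e-48). The miR-27 site ACUGUGA occurred in 325 WT-list loci (0.730%) and 101 KO-list loci (0.247%), an odds ratio of 2.96 (2.36 to 3.69; adjusted exact p = 1.99e-23 over 20 families). For the miR-23 site AAUGUGA the counts were 324 (0.728%) and 125 (0.306%), an odds ratio of 2.39 (1.94 to 2.93; adjusted exact p = 5.48e-17). For the miR-24 site CUGAGCC they were 230 (0.517%) and 102 (0.250%), an odds ratio of 2.07 (1.64 to 2.61; adjusted exact p = 1.63e-09). On the opposite strand of the loci, whose base composition is the complement, the odds ratios were 1.04, 0.848 and 0.835 for miR-27, miR-23 and miR-24. Loci without a 7mer-m8 match of a deleted family made up the great majority of both lists.

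**Figure D2:**
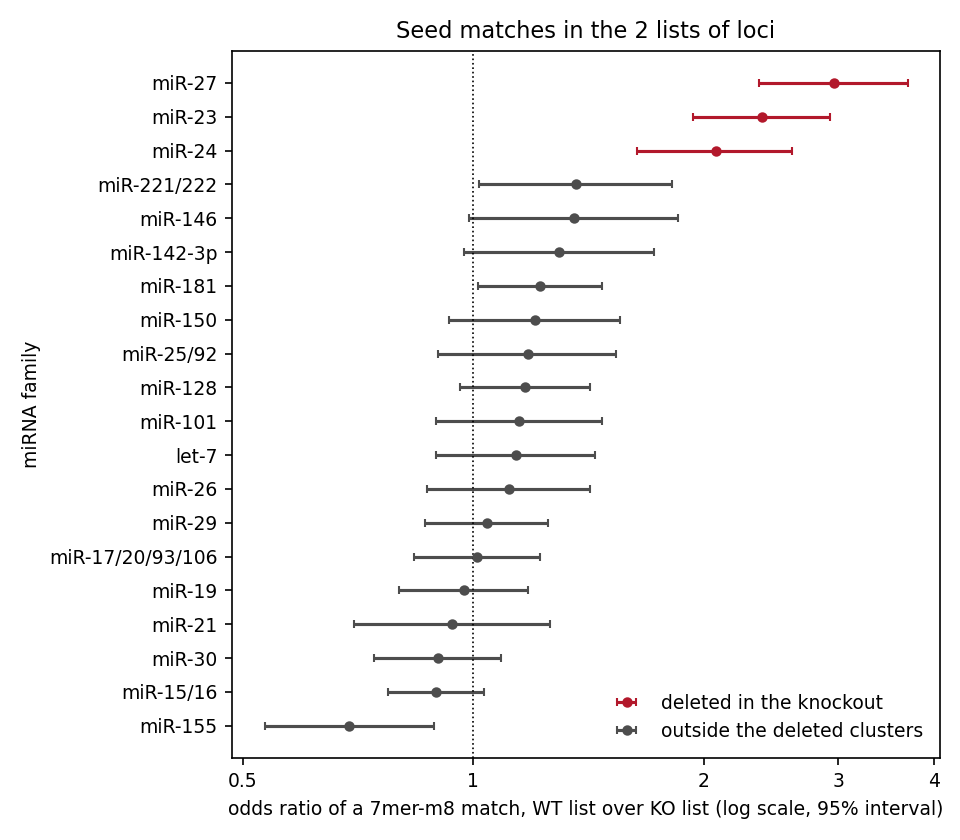
Odds ratio (log scale) of a 7mer-m8 match in WT-list over KO-list loci for each of 20 microRNA families; points are estimates and bars 95% intervals. The 3 deleted families lie between 2.07 and 2.96, and miR-155 lies lowest at 0.689.

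The 17 families outside the deleted clusters served as background measured the same way. Leaving out miR-128, whose site shares 6 bases with that of miR-27, a match of any of the other 16 families stood in 5.86% of WT-list and 5.65% of KO-list loci, an odds ratio of 1.04 (0.981 to 1.101; exact p = 0.191). Of the 17 families, miR-155, a microRNA induced by T cell activation, was the only family past the threshold with 7mer-m8 matches, and toward the KO list: 103 WT-list against 137 KO-list loci, an odds ratio of 0.689 (0.534 to 0.890; adjusted exact p = 0.0218). This call was lost with 8mer matches (0.683, adjusted exact p = 0.242), with 7mer-A1 matches (0.780, adjusted exact p = 0.169), with 1 locus per gene (0.780, adjusted exact p = 0.436) and within 5 kb of the gene end (0.711, adjusted exact p = 0.0747). With 6mer matches miR-155 passed again (0.809, adjusted exact p = 0.0276), as did miR-101 toward the WT list (1.22, 1.09 to 1.37; adjusted exact p = 0.00224), whose 6mer shares 5 bases with the miR-27 site. The miR-101 family did not pass with 8mer (1.24, adjusted exact p = 0.75) or 7mer-A1 matches (1.24, adjusted exact p = 0.169). The miR-128 family passed toward the WT list with 8mer (2.36, adjusted exact p = 0.000529), 7mer-A1 (2.96, adjusted exact p = 9.97e-24) and 6mer matches (1.41, adjusted exact p = 2.28e-09). Its 8mer site contains the 7mer-m8 site of miR-27, and its 7mer-A1 site is the same sequence. On the opposite strand the miR-155 odds ratio was 1.19 (adjusted exact p = 0.888). The activation-linked miR-221 and miR-222 family (1.36, 1.02 to 1.82) and the miR-181 family (1.22, 1.01 to 1.48) had the lowest adjusted exact p of the rest, 0.137 for each. For let-7 the odds ratio was 1.14 (0.894 to 1.44), for miR-29 1.04 (0.866 to 1.25) and for miR-15/16 0.894 (0.774 to 1.03).

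Longer matches differed more between the lists than shorter ones. Over the 3 deleted families, 8mer matches stood in 425 WT-list and 91 KO-list loci, an odds ratio of 4.31 (3.43 to 5.39; exact p = 7.73e-47), and matches of the 6mer alone in 745 and 593 loci, an odds ratio of 1.15 (1.04 to 1.29; exact p = 0.00952). The 8mer odds ratios were 5.04 for miR-27, 4.73 for miR-23 and 3.08 for miR-24. By the authors' quality score (QS), which bins the DBE percentile from 1 to 10, any deleted match had an odds ratio of 2.42 (1.89 to 3.09) at QS 1 to 2, 1.75 (1.41 to 2.16) at QS 3 to 4, 2.56 (1.99 to 3.29) at QS 5 to 7 and 6.50 (4.20 to 9.74) at QS 8 to 10. At QS 8 to 10, miR-23 matches stood in 75 of 2226 WT-list loci and 6 of 2042 KO-list loci (odds ratio 11.8, 4.92 to 24.6), and miR-27 matches in 64 and 8 (7.53, 3.48 to 14.6). There miR-24 matches stood in 31 and 11 loci (2.61, 1.29 to 4.99). At QS 3 to 4 the miR-23 interval included 1 (1.34, 0.952 to 1.87). The ranges were of unequal size: QS 1 to 2 held 22259 of the 44518 WT-list loci and QS 8 to 10 held 2226. Since DBE rose with locus width, they also differ in width, and these odds ratios were not adjusted for it.

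**Figure D3:**
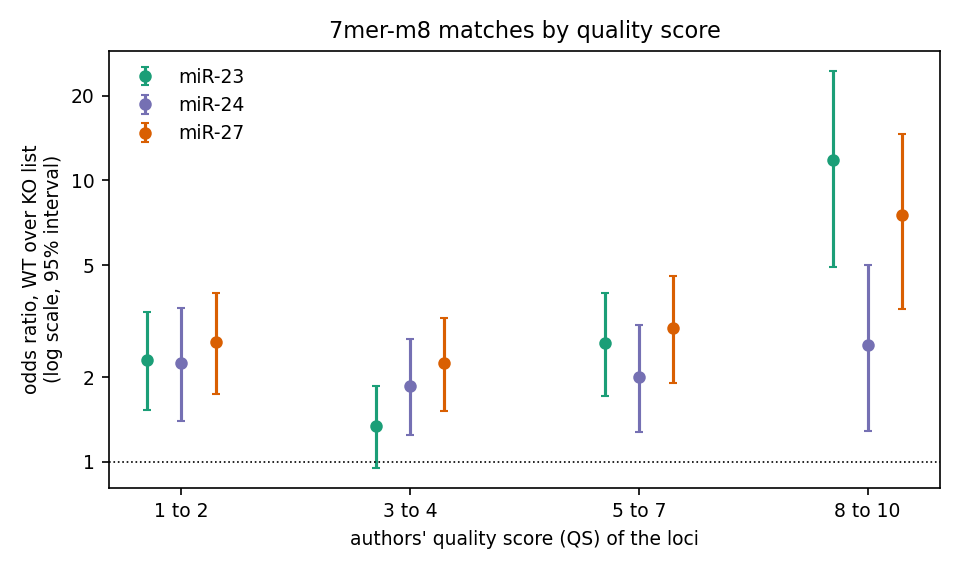
Odds ratio (log scale) of a 7mer-m8 match of miR-23, miR-24 or miR-27 in WT-list over KO-list loci within 4 ranges of the authors' quality score; points are estimates and bars 95% intervals. At QS 8 to 10 the values are 11.8 for miR-23, 2.61 for miR-24 and 7.53 for miR-27.

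The loci with the highest DBE in the authors' deposited table were wide, and more of those in the WT list than in the KO list had a deleted-family match (5 of 15 against 1 of 15, not tested). The highest WT-list locus lay in Celf1, which encodes an RNA-binding protein (chromosome 2, 91015307 to 91015576, DBE 246, miR-23 match). It was followed by loci in Epas1, a hypoxia-inducible transcription factor (chromosome 17, 86832811 to 86832961, DBE 179), Ago2 itself (chromosome 15, 73105315 to 73105505, DBE 173), Armc8 and Tm9sf3. Of the 15 WT-list loci with the highest DBE, 5 had a deleted-family match: Celf1, Ptprc, the leukocyte common antigen (DBE 156), Rnf44, Prkca, a protein kinase C (all miR-23), and Plcxd2 (miR-27 8mer, DBE 141). The other genes were Socs5, Skil, Pik3cg, Rnf4, Xiap and Tmem181c-ps. Of the 15 KO-list loci with the highest DBE, 1 had such a match, the miR-24 match in Ap1g1, a clathrin adaptor subunit (chromosome 8, 109861245 to 109861356, DBE 130). The KO list was led by Camsap2 (chromosome 1, 136270109 to 136270263, DBE 173), Zfp871 (DBE 169) and Arl4c (DBE 163), and these 15 also included Btla, an inhibitory receptor, Lif, a cytokine, and Rc3h2, an RNA-binding protein. Locus width was 102 to 270 bases in the WT-list set and 97 to 192 in the KO-list set.

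Among WT-list loci with a miR-23 match, the highest DBE after those 4 stood in Zfp445 (chromosome 9, 122849594 to 122849742, DBE 130), Dennd1b, Nsd2, a histone methyltransferase, Wwp1, a ubiquitin ligase, Hmgn2 and Yipf6. With a miR-27 match, Plcxd2 (chromosome 16, 45959273 to 45959397) was followed by Gpr174, a receptor of lymphocytes (chromosome X, 107296645 to 107296736, DBE 128), Dynll2, Chd2, Tmcc1, Tmem170b, Ubp1, Ppig, Tmbim6 and Neurl1b. With a miR-24 match, the highest were Hmga1b (chromosome 11, 120763677 to 120763785, DBE 127), Tubb5 (chromosome 17, 35834166 to 35834265, DBE 111), Hmga1 (DBE 104), a locus labelled with both Gm20604 and Moap1, Zfp871, Gfpt1, Ncoa3, Tspyl3, Ahcy and Gpat4. Hmga1b is a near copy of Hmga1, so the placement of those loci is uncertain. The Gfpt1 locus (chromosome 6, 87092090 to 87092192) had 8mer matches of miR-24 and miR-27, and the Ahcy locus (chromosome 2, 155059417 to 155059512) of miR-23 and miR-24. In the KO list, the 5 highest loci with a deleted-family match, in Ap1g1, Ube2z, Stk40, Pml and Ttc39b, all had miR-24 matches.

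No gene list fixed before the data were examined held more genes with an excess of WT-list loci than other genes did, at an adjusted p under the threshold (16 lists, lowest adjusted exact p = 0.406). Of genes outside each list, 44.0% had more WT-list loci. Genes with equal numbers counted as having no excess. Such ties were 2023 of all 7462 genes, but 3 of 32 in cytokine receptor and JAK-STAT signalling, 4 of 36 chromatin and transcription regulators and 6 of 45 reported targets. An odds ratio above 1 can therefore reflect fewer ties, which were not set apart. In cytokine receptor and JAK-STAT signalling, 20 of 32 genes with loci had more WT-list loci (odds ratio 2.12, 1.03 to 4.23; exact p = 0.0481, adjusted exact p = 0.406), with the highest WT-list DBE in Socs5 (151), Pias1 (120) and Jak1 (90.4). In the Th2 programme 12 of 23 genes had more WT-list loci (adjusted exact p = 0.77), and Epas1, Rbpj and Il4ra, the IL-4 receptor chain, had high loci in both lists. In T cell receptor and costimulation signalling the count was 26 of 50 (adjusted exact p = 0.686), led in the WT list by Cd28 (DBE 71.7) and in the KO list by Sos1 (105.6) and Malt1 (105). In apoptosis and cell cycle it was 20 of 35 (adjusted exact p = 0.406), with Xiap (140) and Cdk6 (118) highest in the WT list and Mcl1 (94.5) in the KO list. In TGF-beta and SMAD signalling it was 9 of 20 (adjusted exact p = 1), in PI3K, AKT, mTOR and FOXO signalling 15 of 31 (adjusted exact p = 0.957), in the microRNA pathway 11 of 26 (adjusted exact p = 1), and in other helper and regulatory lineages 10 of 15 (adjusted exact p = 0.406). For chromatin and transcription regulators of T cells the count was 21 of 36 (adjusted exact p = 0.406). Among loci from the 50th percentile of DBE upward, cytokine receptor and JAK-STAT signalling turned to 12 of 31 genes (odds ratio 0.892), the Th2 programme to 8 of 22 (0.807) and apoptosis and cell cycle to 13 of 35 (0.834), each with an adjusted exact p of 1. There the chromatin and transcription list was the only list that passed, with 25 of 35 genes against 41.3% of other genes (odds ratio 3.56, 1.68 to 7.10, adjusted exact p = 0.00633 by Fisher's exact test). Ties were not set apart there either. Markers of other cells were sparse: loci were found in 1 of 13 B cell markers (Ebf1), 2 of 11 CD8 T and NK cell markers, 2 of 14 myeloid, 3 of 10 erythroid and platelet and 2 of 9 stromal and endothelial markers. The highest DBE among these markers was 34.3 (Pecam1, KO list). Those of Gzma, 0.320 in the WT list and 0.510 in the KO list, were near the floor of each list. The adjusted exact p of these 5 lists was 0.77, 0.77, 1, 1 and 0.77. The list of deleted microRNA loci had 1 of 12 labels with loci, 2010111I01Rik (adjusted exact p = 0.77).

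Genes reported as targets of miR-23, miR-24 or miR-27, a list from background knowledge that includes genes reported in helper T cells and is not independent evidence, had 26 of 45 genes with more WT-list loci (odds ratio 1.74, 0.964 to 3.12; adjusted exact p = 0.406). Their loci with a deleted-family match numbered 20 in the WT list, in 18 genes, and 4 in the KO list, an odds ratio of 4.74 (1.55 to 12.05; adjusted exact p = 0.0269 over 16 lists). The interval includes the 2.48 found over all loci, so no difference from other genes was shown. This count of matching loci per list was added after the data were seen. Matching WT-list loci included miR-23 sites in Rora, a nuclear receptor (chromosome 9, 69382777 to 69382868, DBE 98.5), and Smad3, a TGF-beta signal transducer (chromosome 9, 63648970 to 63649082, DBE 92.4). They also included miR-27 sites in Foxo1, a transcription factor of T cell quiescence (chromosome 3, 52347384 to 52347464, DBE 83.1), Cd28, a costimulatory receptor (chromosome 1, 60770761 to 60770834, DBE 71.7), Ppif (DBE 68.2) and Runx1 (DBE 55.0). The 4 matching KO-list loci were in Clcn3, Xiap, Socs6 and E2f2. Other listed genes had loci without a match. Il4 had 3 WT-list and 3 KO-list loci and Gata3 had 7 and 5, with 0 matches of a deleted family. In the microRNA pathway list, Ago2 had a WT-list locus with a miR-27 match (chromosome 15, 73106128 to 73106207, DBE 83.2), and 8 WT-list and 2 KO-list loci matched (adjusted exact p = 0.5). Genes in this paragraph outside the naming rule, Ppif, Socs6, E2f2, Il4 and Gata3, were chosen after their values were seen.

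Without reference to known families, 7-mers were ranked by their share of loci in the WT list over the KO list. Among the 9170 7-mers found in at least 100 loci, ACUGUGA of miR-27 ranked 1, AAUGUGA of miR-23 ranked 5 and CUGAGCC of miR-24 ranked 16. Among all 7-mers, rare ones included, they ranked 143, 287 and 464, and with 1 locus per gene 387, 410 and 885. Of the common 7-mers, 63 passed Fisher's exact test after adjustment, all toward the WT list and 0 toward the KO list. Of these 63, 11 held a 6mer of a deleted family and 17 more shared 5 bases with an 8mer site. A further 14 had 5 or more G, 7 had 5 or more C, and 14 fell in none of these classes.

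Loci with a deleted-family match had higher DBE than loci without one in both lists. In the WT list the median DBE was 29.8 with a miR-23 match (interquartile range 17.8 to 49.1) against 18.0 without (11.3 to 27.3), 26.7 against 18.1 for miR-24 and 27.6 against 18.1 for miR-27. The permutation test gave an adjusted p of 1e-05 for each, the smallest it can give. In the KO list the differences were 6.30, 8.38 and 7.88 (adjusted permutation p = 5e-05, 1.5e-05 and 1.5e-05). DBE rose with locus width across loci, which are not independent replicates (Pearson's r 0.885 in the WT list and 0.901 in the KO list, Spearman's rho 0.894 and 0.913), and matching loci were wider. Against loci of the same width, the WT-list differences were 1.53 for miR-23 (adjusted permutation p = 3e-05), -0.781 for miR-24 (adjusted permutation p = 0.00217) and 0.463 for miR-27 (adjusted permutation p = 0.0206), and the KO-list differences -0.179, 1.06 and -0.576 (adjusted permutation p = 0.525, 0.00963 and 0.13). In loci of 21 or more bases, the positions that a match can take were divided into 3 equal parts. The middle part held 36.8% of 799 WT-list and 30% of 300 KO-list matches of the deleted families. The odds ratio of 1.36 (1.02 to 1.80) did not pass Fisher's exact test after adjustment (adjusted exact p = 0.0788).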

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

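The odds ratios stratified by width and gene, shuffling, leaving out 20 genes, the central 20 bases, gene ends, loci outside the reported targets, common 7-mers, width-adjusted DBE, the RNA classes, leaving out Kcnq1ot1, matching loci of the reported targets, site position between the lists, every alternative for miR-155 and 2 checks from the 50th percentile of DBE upward were tests chosen after the data were seen. For each of miR-23, miR-24 and miR-27, 14 alternatives changed the loci, the sites or the estimate, and 13 kept the direction and either an adjusted p under the threshold or, for stratification and shuffling, which give no p, an interval that excludes 1, with ranges of 1.71 to 5.95, 1.66 to 3.08 and 1.75 to 5.42. The exception was the opposite strand, with 0.848, 0.835 and 1.04, and 1.19 for miR-155. That strand is not the RNA sequence listed for a locus, so the lack of an excess there does not go against the result. Its composition is the complement and thus no background of these sequences, and the cause of its values was not tested. Merging loci and removing overlapping loci could change nothing, since no loci overlapped. The 14 alternatives are not independent support. Every 8mer match is also a 7mer-m8 match. The reported targets held 20 of the 875 matching WT-list loci, and the 20 genes left out held few each, so leaving out either could hardly change the call. For miR-155, 9 of 14 alternatives kept the call, and the threshold was missed with 8mer (0.683) and 7mer-A1 sites (0.780), 1 locus per gene (0.780) and loci near gene ends (0.711); 8mer sites and 1 locus per gene leave fewer loci, and the cause was otherwise not tested.

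Allowing 100 bases raised the overlap of WT-list loci from 0 to 68.8%. From the 50th percentile of DBE upward, the long noncoding RNA odds ratio turned to 0.774 and 1 gene list passed instead of 0; the cause was not tested. Without Kcnq1ot1, which held 121 WT-list and 65 KO-list loci, the long noncoding RNA odds ratio was 1.12 and no longer passed. With 1 locus per gene the ranks of miR-23, miR-24 and miR-27 moved to 410, 885 and 387. Among common 7-mers they were 5, 16 and 1, since rare 7-mers with extreme ratios were left out. Set against loci of the same width, the DBE difference turned to -0.781 for miR-24 in the WT list and to -0.179 and -0.576 for miR-23 and miR-27 in the KO list. No paired analysis was possible because the Th2 tables rest on 1 sample per genotype. Extension by 25 bases, a window of 60 bases, restriction to 3' UTRs or exons and the annotation classes were not run. Read depth is unknown, so its effect on the lists was not tested.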

Other observations

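The test of wider loci was chosen after the result was seen, as were the 10 random seeds of the shuffles, which were added after a first value from 1 seed, and the counts of matching loci per gene list. The tests by gene, by shuffling and without 20 genes were added once the odds ratios were known, before their own values were seen.

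In 50 genes the WT list had matching loci for 2 or more deleted families, and in 3 of them, Hic1, Kcnq1ot1 and Stk35, for all 3; in the KO list the counts were 5 and 1. The difference was not tested, and no count expected from unrelated matches was computed. The WT list held more matching loci in all (875 against 328), and genes such as Kcnq1ot1 had many loci (121 in the WT list). These counts therefore do not show shared targeting by the families. TGF-beta and SMAD genes had 6 WT-list loci with a deleted-family match, in Smad3, Tgfbr1, Smad1, Ski, Furin and Zeb1, against 0 in the KO list (exact p = 0.0305, adjusted exact p = 0.244 over 16 lists). Genes of other helper and regulatory lineages had 4 such WT-list loci, in Rora (miR-23 and miR-27), Runx1 and Ikzf2, against 0 (adjusted exact p = 0.5). Smad3, Tgfbr1, Furin, Rora and Runx1 are also in the list of reported targets, so their loci are counted there too. Cytokine receptor and JAK-STAT genes had 1 matching WT-list locus against 2 in the KO list, apoptosis and cell cycle genes 2 against 3, and chromatin and transcription regulators 2 against 3 (odds ratios 0.423, 0.600 and 0.594; adjusted exact p = 1 for each). The counts were 7 against 3 in PI3K, AKT, mTOR and FOXO signalling, 6 against 2 in T cell receptor signalling and 2 against 0 in the Th2 programme (adjusted exact p = 0.921, 0.921 and 1). The 7-mer GAGGUAG, the let-7 seed sequence itself and not its target site, was in 80 WT-list and 31 KO-list loci (odds ratio 2.37, adjusted exact p = 0.00712), while the let-7 target site had an odds ratio of 1.14. Hic1, Kcnq1ot1, Stk35, Smad1, Ski, Furin and Zeb1 and this 7-mer were chosen after their values were seen.

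The pattern weighed first was the excess of WT-list loci with a match of a deleted family. Stratification by locus width left odds ratios of 2.20, 1.94 and 2.78 for miR-23, miR-24 and miR-27 (lowest lower bound 1.53). Stratification by gene, which holds RNA abundance and the number of loci of a gene fixed, left a lowest lower bound of 1.58. These values argue against width and against gene-level differences as the whole cause. Leaving out 20 genes left a lowest lower bound of 1.54. Those genes held only 2 to 4 matching WT-list loci each, so leaving them out could hardly remove the excess and decides nothing. The 875 matching WT-list loci lay in 790 genes, with at most 4 in a gene, which argues against a few genes as the whole cause. For miR-23, miR-24 and miR-27, observed over dinucleotide-shuffled counts were 2.06, 2.00 and 2.31 in the WT list. In the KO list they were 1.05, 1.06 and 0.919. WT over KO list, this gave 1.97, 1.88 and 2.51, with intervals that excluded 1 for each family with all 10 seeds. These values argue against composition as the whole cause. The bound of 1.5 set beforehand was missed for miR-24 with 1 seed (lowest lower bound 1.49), so the test did not pass as set. Shuffled loci alone, which keep their widths, gave ratios of 1.21, 1.097 and 1.18, against odds ratios of 2.39, 2.07 and 2.96. What shuffles keep thus made up the smaller part of each excess, and its exact share was not estimated. The odds ratio of 8mer matches was 3.74 times that of 6mer-only matches, with intervals that did not overlap, which is in line with loss of the deleted microRNAs from AGO2 as a candidate explanation. With 1 Th2 sample per genotype, differences between the libraries other than genotype stay open and untested.

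A second pattern was the set of 14 called 7-mers with 5 or more G, with a pooled odds ratio of 1.55 (1.41 to 1.70). Shuffled loci alone gave a ratio of 1.35, and observed over shuffled counts left 1.14 (1.06 to 1.22). Shuffles that keep the dinucleotides of a short locus also largely keep its runs of G or C. The shuffled ratio can therefore hold part of the signal itself, so shuffling cannot separate a G-rich or C-rich motif from composition. The 7 called 7-mers with 5 or more C had 1.56 (1.40 to 1.74), a shuffled ratio of 1.26, and 1.23 (1.12 to 1.36) after shuffling, with a lower bound of 1.11 or more with every seed. For the G-rich set the lower bound was under the 1.1 set beforehand, for the C-rich set no bound was set, and both were selected because they were called, so whether composition is the whole cause cannot be told apart; no biological explanation was tested.

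One hypothesis was that passenger strands of the deleted hairpins also guided AGO2 in wild-type cells. Their 7mer-m8 sites, pooled, stood in 236 WT-list and 220 KO-list loci, an odds ratio of 0.984 (0.818 to 1.18, exact p = 0.888 by Fisher's exact test). This argues against a pooled excess of 1.5 or more. For miR-27a-5p alone the odds ratio was 1.11 (0.722 to 1.70), so such an excess for that strand stays open. Another hypothesis was that pairing of microRNA nucleotides 13 to 16 adds to the seed match. Such pairing was found upstream of 51 of 440 WT-list and 12 of 142 KO-list matches, an odds ratio of 1.42 (0.721 to 2.64; exact p = 0.352), too few to decide.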
